A study of Macaca mulatta with 252 samples.

How the data were processed

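RNA from laser-captured pieces of rhesus macaque brain was measured on GeneChip Rhesus Macaque Genome arrays, 1 array per piece. There were 225 experimental arrays in 57 region groups, of which 54 held 4 arrays and 3 held 3 arrays (layers 4 and 5 of A1 and layer 2 of M1). They came from 6 animals, 3 male and 3 female, named here male A, B and C and female D, E and F. A further 27 control arrays held a commercial whole brain RNA pool (15 arrays), CA3 tissue (9) and MT tissue (3). The control arrays entered no tissue comparison.

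The deposited values are log10 intensities, per the file headers, and they were multiplied by the log2 of 10 so that all changes here are on the log2 scale. Per the file headers, the authors computed RMA within each amplification batch in Matlab and then scaled each probe set on the whole brain control samples common to the batches. The plan had assumed log2 values; the log base was settled from the headers and the range of the table before any comparison was run. The array medians lay between 4.72 and 5.00 on the log2 scale. The correlation of an array with the mean of the other arrays of its group had a median of 0.983 and a lowest value of 0.941. No pair of experimental arrays was identical (highest correlation 0.992). For arrays, the number of arrays and animals limits the precision.

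Of 52865 probe sets, 24969 carried 1 gene symbol, 361 carried several and 27535 carried none. Probe sets with exactly 1 symbol were kept, and each gene was represented by its probe set with the highest mean over the 225 experimental arrays, which gave 14133 genes. The symbols were those of the deposited platform annotation, and 24629 of the probe sets with 1 symbol had their Entrez ID in the macaque RefSeq gene list, and all 24629 had the same symbol there. That list served for names alone, so no coordinates are given. In each comparison a gene was tested when its mean over the units of that comparison exceeded the median of all probe sets.

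The unit of each comparison was chosen so that an animal counted once per level. For the layers, the values of each animal and area were centred, then averaged per layer over the areas with layers 2 to 6 (ACG, OFC and M1, with no layer 4 array, and V1, with a divided layer 4, were left out there), in animals with at least 3 such areas. For the contrast of layers 5 and 6 with layers 2 and 3, all 10 areas were used in the same way. For the areas, layers 2, 3, 5 and 6 were averaged per animal and area. The difference between deep and upper layers in V1 was compared with the mean of that difference in the other 9 areas of the same animal. For the layers of V1, the hippocampal fields and the divisions of the lateral geniculate nucleus (LGN), the arrays themselves were the units. Layers 4Ca and 4Cb of V1 were averaged per animal for the contrast with layer 4 of V2, and the structures were compared with 1 mean per animal and structure. Males were compared with females in the 4 animals that had arrays of nearly all regions, and the pool was compared across its 3 array sets.

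Linear models were fitted across all genes with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8 for reading), with animal as a fixed block, moderated statistics and Benjamini-Hochberg adjustment. A gene was called when its adjusted p was under 0.05 and its log2 change was at least 1; for moderated F statistics over several levels, the range of the fitted means had to be at least 1. Errors printed as ± are standard errors of the fitted log2 change unless SD is written. The pairing by animal was checked: after removal of the group means, arrays of 1 animal from different groups correlated across genes with a median r of 0.194 (5367 pairs), against -0.0563 for arrays of different animals (19500 pairs).

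Gene lists for cell types, layers, regions, receptors and pathways were fixed before the data were examined, as were the comparisons, thresholds, alternatives and the rule for named genes. There were 30 lists, of which 28 had measured genes and 2, made of genes on the sex chromosomes, had none. For each list the text gives the called members and the count adjusted over the list alone, together with limma's camera test at a preset inter-gene correlation of 0.01 and with the correlation estimated from the data. Named genes are the 6 largest increases and the 6 largest decreases among called genes that changed the same way in every animal, with LOC symbols passed over, and up to 4 called members of each list. Where no gene was called, the 3 highest and 3 lowest by moderated t are named.

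The labels name 3 amplification batches but do not say which experimental array belongs to which. The spread of the cre hybridisation control probes split the regions into 2 control sets, which are used here as a stand-in for batches: a narrow set (A1, ACG, M1, S1, TE, V1) and a wide set (DLPFC, MT, OFC, V2, hippocampus, LGN). Comparisons between areas were therefore repeated within each control set, a choice made after seeing the data.

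The alternatives were no filter on dim genes, a filter at the 75th percentile, the mean of a gene's probe sets, a second quantile normalisation, limma with trend and robust settings, no animal block, each array as a unit, all 6 animals for sex, and each animal left out in turn. Added after seeing the data were the level of the poly-A control probes as a covariate and fits within the control sets. The models were tested on simulated data with 200 changed genes: changes of 1.5 and 2 on the log2 scale were found in at least 97.0% of cases. At a change of 1, adjusted p under 0.05 was reached by 83.6% of genes for 4Ca against 4Cb, 80.3% for magnocellular against parvocellular and 88.1% for sex. The simulated noise of a gene was the same in every array, so the share for 4Ca against 4Cb may be too high, since V1 arrays were the least alike. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.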

Results

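Gene expression was measured in 10 areas of the macaque neocortex divided by layer, in 4 hippocampal fields (CA1, CA2, CA3 and the dentate gyrus, DG) and in 3 divisions of the LGN. The areas were anterior cingulate gyrus (ACG), orbitofrontal cortex (OFC), dorsolateral prefrontal cortex (DLPFC), primary motor (M1), somatosensory (S1) and auditory (A1) cortex, the visual areas V1 and V2, the middle temporal area (MT) and temporal area TE. Cortical arrays numbered 45 for female D, 49 for female E, 39 for male A and 46 for male C, with 13 for male B and 5 for female F. Only female D, female E, male A and male C had hippocampal arrays (4 each) and LGN arrays (3 each). Values below are from 4 animals unless another number is given.

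The variation between cortical arrays was divided among area, layer and animal. Over 158 arrays of layers 2, 3, 5 and 6 and 10316 genes, the median share of the sum of squares was 18.4% for area, 6.16% for layer, 13.3% for area with layer, 5.31% for animal and 45.5% for the residual. Layer accounted for 91.8% of the variation of CUX2, a homeobox transcription factor of upper layer neurons, and for 88.7% of that of FEZF2, a transcription factor of neurons that project below the cortex. Area accounted for 76.2% of the variation of PACC1, a chloride channel, 70.8% of that of SYT17, a synaptotagmin, and 70.3% of that of SKIC8, which split by control set. Area has more levels than layer and each area lies in a single control set, so its share also holds any batch difference and is not comparable with that of layer.

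The control probes on the arrays differed between regions. The SD of the cre hybridisation controls lay between 0.0708 and 0.111 in the narrow control set (121 arrays) and between 0.174 and 0.268 in the wide set (104 arrays). The poly-A controls, which are added to the RNA and read higher where less RNA was amplified, had means of 9.99 ± 0.57 (SD, 32 arrays) in V1 and 9.83 ± 0.67 (SD, 20 arrays) in V2 against 8.47 to 9.33 in the other areas. The hybridisation controls of V1 (mean 12.5) lay above those of the rest of its control set (11.4 to 11.8) and level with those of V2 (12.5), so sharing a control set does not show a shared batch. Across genes, the wide minus narrow difference of the areas correlated with the difference of the pool between its set 1 and set 2 (r = -0.224), but 14 of the 210 possible splits of the areas into 4 and 6, the real one among them, correlated as strongly. The arrays of V1 also correlated less with the mean of the other arrays of their group than those of any other area (mean 0.966).

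The first question was which genes mark the layers of the cortex. Over areas with layers 2 to 6, 681 of 10299 genes differed among the layers (6418 at adjusted p alone). Layer 2 had 127 genes higher and 152 lower than the mean of the other layers (4605 at adjusted p alone), layer 3 had 29 and 38, layer 4 had 36 and 44, layer 5 had 39 and 32, and layer 6 had 98 and 70. In the lists below, the called counts adjusted over the list alone equalled those adjusted over all genes, with 1 exception given where it occurs. Of 1053 camera tests of a list in a contrast, 230 were called with the preset correlation and 30 of these held with an estimated correlation: 8 in the layer contrasts, 1 in A1 and 21 among the layers of V1.

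Layer 2 stood apart by high CUX2 (3.31 ± 0.08, a 9.93-fold difference), RBP4 (retinol-binding protein, 3.29 ± 0.15), PCDH8 (a protocadherin, 3.29 ± 0.12) and MCOLN3 (3.27 ± 0.25). NEUROD6, a transcription factor of excitatory neurons, was 9.29-fold lower (-3.22 ± 0.13), C1S was lower by 8.67-fold and HS3ST2 by 7.36-fold. Of 8 tested upper layer neurons genes, 5 were higher, 0 lower and 3 not called, among them CARTPT (a neuropeptide precursor, 2.17 ± 0.17), HPCAL1 (2.09 ± 0.09) and RASGRF2 (2.07 ± 0.05); the list was called with the preset (adjusted p = 3.92e-06) and the estimated correlation (adjusted p = 0.0149). Of 6 myelin and oligodendrocytes genes, 4 were lower and 2 not called, with UGT8, an enzyme of myelin lipid synthesis, at -2.12 ± 0.10 and MBP, myelin basic protein, at -2.02 ± 0.10 (adjusted p = 4.1e-06, and 0.0394 with an estimated correlation). Among 7 inhibitory neurons genes, VIP was higher (1.83 ± 0.08), PVALB was lower (-1.13 ± 0.12) and 5 were not called. Of 8 perineuronal net and matrix genes, 3 were lower and 5 not called, including the proteoglycan ACAN and its link protein HAPLN4 (-1.19 ± 0.12); the camera call (adjusted p = 0.0185) was lost at adjusted p = 0.171 with an estimated correlation.

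Layer 3 shared high CUX2 (3.08 ± 0.08) and was marked by FREM3 (2.48 ± 0.26), NTNG1 (an axon guidance protein, 2.00 ± 0.09) and MET (the receptor of hepatocyte growth factor, 1.89 ± 0.19). FEZF2 was 5.77-fold lower there. Of 15 oxidative phosphorylation genes, 0 were called by limma at the log2 threshold, and 12 were higher at adjusted p alone with a list median of 0.16; the camera call (adjusted p = 0.000454) was lost at adjusted p = 0.386 with an estimated correlation. In layer 4, TLL1 (2.37 ± 0.14), TSHZ2 (2.03 ± 0.11), PVALB (1.65 ± 0.12) and RORB (1.60 ± 0.15), a nuclear receptor of neurons receiving thalamic input, were higher. RBP4 fell by 2.58 and GBP1 fell by 2.54. RORB was the 1 called gene of 5 layer 4 neurons genes, with 4 not called (adjusted p = 0.0123, and 0.0942 with an estimated correlation). Of 3 primary visual cortex genes, 0 were called by limma at the log2 threshold and 2 were higher at adjusted p alone (camera adjusted p = 0.0123, and 0.0942 with an estimated correlation).

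Layer 5 was marked by FEZF2 (2.19 ± 0.12), HS3ST2 (2.02 ± 0.08), GRP (gastrin-releasing peptide, 2.01 ± 0.13), RSPO3 (1.83 ± 0.09) and RXFP1 (a relaxin receptor, 1.80 ± 0.15). Of 8 layer 5 neurons genes, 4 were higher and 4 not called, with ETV1 at 1.48 ± 0.07, SULF2 at 1.09 ± 0.07 and CRYM at 1.02 ± 0.13 (adjusted p = 1.38e-07, and 0.0251 with an estimated correlation). Layer 6 was marked by SYT6 (2.77 ± 0.10), ZFHX3 (2.51 ± 0.08), KRT16 (2.41 ± 0.12) and SOSTDC1 (2.24 ± 0.14). There CUX2 was 13.6-fold lower (-3.76 ± 0.08), and BHLHE22 (-3.46 ± 0.10), TAFA1 (-3.02 ± 0.11) and MET (-2.85 ± 0.19) were lower too. The symbol KRT16 is that of the array annotation and was not checked against the genome. Of 10 layer 6 neurons genes, 2 were higher and 8 not called (adjusted p = 0.0036, and 0.242 with an estimated correlation). Of 6 myelin and oligodendrocytes genes, 4 were higher in layer 6 and 2 not called, UGT8 by 1.44 ± 0.10 and MBP by 1.25 ± 0.10 (adjusted p = 1.96e-06, and 0.0556 with an estimated correlation). VIP (-2.13 ± 0.08) and PVALB (-1.85 ± 0.12) were the 2 lower genes of the 7 inhibitory neurons genes, with 5 not called.

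The contrast of layers 5 and 6 with layers 2 and 3 asked what separates deep from upper layers over all 10 areas. In 5 animals, 128 genes were higher and 91 lower in the deep layers, of 10316 tested (3963 at adjusted p alone). FEZF2 was 13.9-fold higher (3.80 ± 0.09), followed by KRT16 (3.37 ± 0.10), HS3ST2 (3.20 ± 0.06) and ANLN (2.79 ± 0.10). CUX2 was 33.2-fold lower (-5.05 ± 0.05), FREM3 14.6-fold lower and PCDH8 13.3-fold lower. VIP fell by 2.16 and GRIA4, a glutamate receptor subunit, fell by 1.28, while NEUROD6 was higher (2.40 ± 0.13). Of the 8 upper layer neurons genes, 4 were lower and 4 not called (adjusted p = 1.43e-06, and 0.031 with an estimated correlation), and of the 8 layer 5 neurons genes, 4 were higher and 4 not called (adjusted p = 0.000774, and 0.031 with an estimated correlation). Of the 6 myelin and oligodendrocytes genes, 4 were higher and 2 not called (adjusted p = 7.28e-06, and 0.136 with an estimated correlation).

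**Figure D1:**
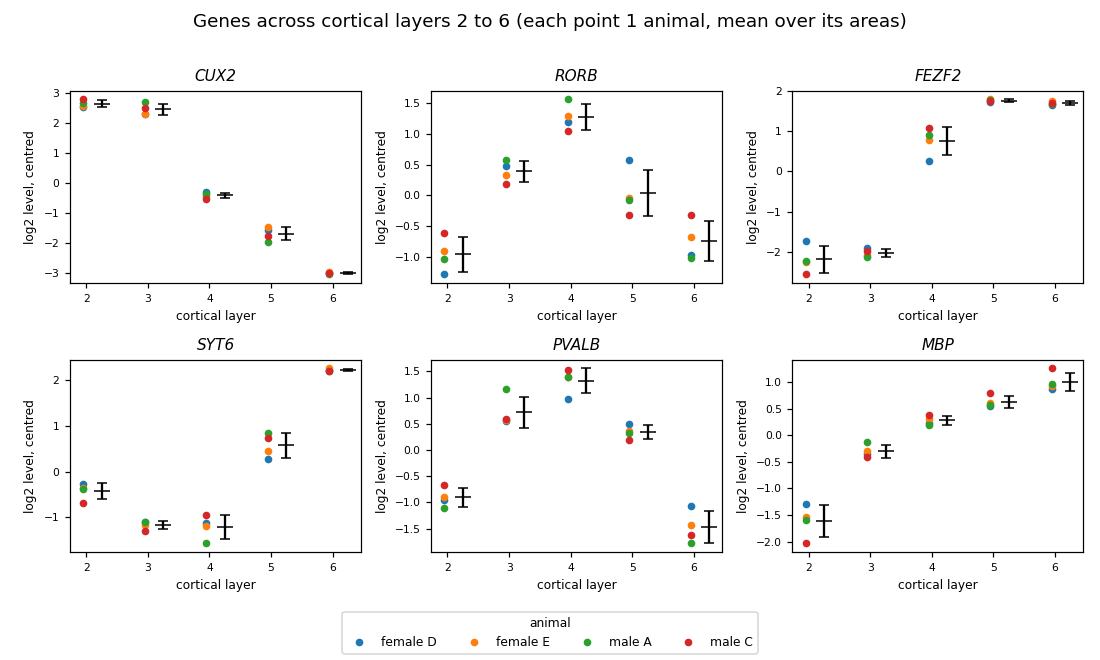
Expression of 6 genes in cortical layers 2 to 6, as log2 intensity after centring within animal and area; points are animals and bars are the mean ± SD (4 animals). CUX2 fell from 2.65 in layer 2 to -3.01 in layer 6, RORB and PVALB were highest in layer 4 (1.28 and 1.32), FEZF2 was highest in layers 5 and 6 (1.75 and 1.70), and SYT6 was highest in layer 6 (2.21).

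The second question was how the areas differ. There were 947 genes differing among the 10 cortical areas, of 10309 tested (7906 at adjusted p alone; 6 animals). Tests chosen after seeing the data gave 728 genes within the 6 areas of the narrow control set, 145 within the 4 areas of the wide set, and 739 with control set as a block. V1 and ACG were the pair with the most called genes (420), and the median was 76 for the 21 pairs of the same control set and 80.5 for the 24 pairs of different sets. Against the mean of the other 9 areas, 122 genes were called in ACG, 123 in V1, 51 in V2, 26 in M1, 14 in OFC, 14 in MT, 11 in A1, 7 in TE, 5 in DLPFC and 4 in S1.

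In V1, 12 genes were higher and 111 lower than in the other areas (4603 at adjusted p alone). PVALB, a calcium-binding protein of fast-spiking interneurons, was 3.79-fold higher (1.92 ± 0.26), CLMP, an adhesion molecule, was higher by 1.84 ± 0.14, and FSTL1, a secreted follistatin-like protein, by 1.35 ± 0.10. RBP4 was 19.8-fold lower (-4.31 ± 0.30), SYT17 8.58-fold lower (-3.10 ± 0.17), GBP1 8.48-fold lower (-3.08 ± 0.20) and RASGRP1 5.62-fold lower (-2.49 ± 0.12). Also lower were ROBO1, a receptor in axon guidance (-2.08 ± 0.11), CRYM (-1.98 ± 0.13), P2RY12, a receptor of microglia (-1.60 ± 0.14), NPY (-1.48 ± 0.19), PNMA5 (-1.47 ± 0.12) and GABRA3, a GABA-A receptor subunit (-1.08 ± 0.14). Against the other areas of the narrow control set, V1 had 15 genes higher and 201 lower; PVALB was then higher by 2.07 ± 0.27 and FSTL1 by 1.41 ± 0.11, while RBP4 was at -4.65 ± 0.31, SYT17 at -3.59 ± 0.17 and GBP1 at -3.55 ± 0.21. Of the 123 genes, 119 were called in that contrast in the same direction, but the V1 arrays are shared and a batch of V1 alone cannot be told apart from area. With the poly-A control level as a covariate, chosen after seeing the data, 147 genes were called and 1775 passed adjusted p alone.

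Among gene groups in V1, 1 of 7 fast spiking channels genes was higher and 6 not called, with 6 higher at adjusted p alone (camera adjusted p = 0.000546, and 0.205 with an estimated correlation). FSTL1 was the 1 higher gene of the 3 primary visual cortex genes, with 2 not called (adjusted p = 0.0205, and 0.174 with an estimated correlation). RBP4 and PNMA5 were the 2 lower genes of the 4 association cortex genes, with 2 not called; that list was not called by camera (adjusted p = 0.0899). Of 6 endothelium genes, 0 were called by limma at the log2 threshold and 5 were lower at adjusted p alone (adjusted p = 0.0434, and 0.205 with an estimated correlation). Both receptor lists were lower in V1 by camera: of 4 GABA-A receptors genes, 1 was lower and 3 not called, and of 4 ionotropic glutamate receptors genes, 0 were called at the log2 threshold and 4 were lower at adjusted p alone (adjusted p = 0.0132 for each, and 0.174 with an estimated correlation).

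V1 and V2 together were compared with ACG, OFC and DLPFC to set early visual against frontal cortex. In the visual areas 21 genes were higher and 131 lower (4401 at adjusted p alone). PVALB was 6.24-fold higher (2.64 ± 0.24), with MET (1.92 ± 0.22), LTB (1.86 ± 0.11), MAB21L1 (1.62 ± 0.11), FSTL1 (1.57 ± 0.09), HAPLN4 (1.19 ± 0.13) and the neurofilament NEFH (1.00 ± 0.11). RBP4 was 25.9-fold lower (-4.70 ± 0.28), GBP1 10.9-fold, SYT17 10.6-fold and ADAMTS3 7.24-fold lower; ROBO1 (-2.13 ± 0.11), CRYM (-2.03 ± 0.12), PNMA5 (-1.64 ± 0.11), EFNB3 (-1.33 ± 0.09) and GRIA1 (-1.10 ± 0.09) were lower as well. Of 7 fast spiking channels genes, 2 were higher and 5 not called, with 7 higher at adjusted p alone (adjusted p = 1.54e-08, and 0.0559 with an estimated correlation). Of 20 axon guidance genes, 3 were lower and 17 not called (adjusted p = 0.00282, and 0.198 with an estimated correlation). With the poly-A covariate 1419 passed adjusted p alone. Within control sets, 31 genes were higher and 157 lower, PVALB by 2.86 ± 0.24 and RBP4 at -4.85 ± 0.28.

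ACG had 74 genes higher and 48 lower. RBP4 was 6.54-fold higher (2.71 ± 0.31), followed by CALML4 (2.45 ± 0.12), ADAMTS3 (2.29 ± 0.16), GRP (2.17 ± 0.14) and FOXO6 (2.06 ± 0.17), and PNMA5 was higher by 1.37 ± 0.12. MET was 6.44-fold lower (-2.69 ± 0.25), PVALB 5.31-fold lower (-2.41 ± 0.27) and MBP 2.54-fold lower (-1.35 ± 0.11), and the sodium channel SCN1A was lower (-1.16 ± 0.12). Of 7 fast spiking channels genes, 2 were lower and 5 not called (adjusted p = 3.32e-08, and 0.0597 with an estimated correlation). The myelin and oligodendrocytes list (6 tested) had 2 lower and 4 not called (adjusted p = 5.65e-06, and 0.0597 with an estimated correlation). Of 4 association cortex genes, 2 were higher and 2 not called (adjusted p = 0.0012, and 0.0597 with an estimated correlation). Within the narrow control set, ACG had 65 genes higher and 58 lower, with RBP4 at 2.93 ± 0.33 and PVALB at -2.60 ± 0.28.

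M1, with 3 animals, had 25 genes higher and 1 lower. ANLN (1.65 ± 0.18), RFTN2 (1.62 ± 0.15), NEFH (1.46 ± 0.14), UGT8 (1.35 ± 0.15), SPP1 (osteopontin, 1.33 ± 0.13), ACAN (1.13 ± 0.13) and PVALB (1.10 ± 0.30) were higher, and EPHA3, a guidance receptor, was lower (-1.48 ± 0.27). Of 5 large axon and magnocellular markers genes, 3 were higher and 2 not called (adjusted p = 7.68e-06, and 0.0743 with an estimated correlation), and of 6 myelin and oligodendrocytes genes, 1 was higher and 5 not called (adjusted p = 6.55e-07, and 0.0743 with an estimated correlation). Within its control set M1 had 26 genes higher and 3 lower, with ANLN at 1.84 ± 0.18 and NEFH at 1.53 ± 0.15.

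The remaining areas differed in fewer genes. V2 had 3 genes higher and 48 lower (3 and 37 within its control set), with LTB at 1.26 ± 0.12, PVALB at 1.05 ± 0.26, RBP4 at -2.06 ± 0.30, ADAMTS3 at -2.05 ± 0.15 and SYT17 at -1.99 ± 0.17. MT, where 3 animals also had other areas, had 7 higher and 7 lower (20 and 5 within its set), with MET at 1.63 ± 0.27, FOXO6 at -1.30 ± 0.19 and GRP at -1.30 ± 0.16. TE had 6 higher and 1 lower (3 and 3), with MET at 1.97 ± 0.24 and CARTPT at 1.26 ± 0.13. A1, with 3 animals, had 10 higher and 1 lower (7 and 1), with GRP at 1.34 ± 0.16 and BHLHE22 at 1.27 ± 0.19. The upper layer neurons list was called higher in A1 by camera (adjusted p = 0.000389, and 0.0264 with an estimated correlation), although 0 of its 8 genes were called by limma at the log2 threshold and 4 were higher at adjusted p alone. The 4 genes of S1 were RFTN2 (1.21 ± 0.13), EVI2A (1.04 ± 0.17), KMO (1.03 ± 0.11) and ANLN (1.03 ± 0.15), against 5 within its set.

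OFC had 4 genes higher and 10 lower, and DLPFC had 3 higher and 2 lower. RBP4 was higher in both, by 1.78 ± 0.31 in OFC and 1.61 ± 0.31 in DLPFC, in 3 of 4 animals each. The exception was male B, whose only areas were ACG, OFC and DLPFC, so its reference held no other area. MET (-1.33 ± 0.25) and MAB21L1 (-1.14 ± 0.13) were lower in DLPFC. LOC719477, named after its values were seen because it fell outside the naming rule, was the remaining gene called in DLPFC (1.12). HBB, a haemoglobin chain, was higher in OFC (1.02 ± 0.15) and DLPFC (1.09 ± 0.15), and SKIC8 was called lower in OFC, but against the areas of the same control set HBB was at 0.02 and 0.10 and SKIC8 at -0.35. Within the control set OFC had 10 genes higher and 11 lower, and DLPFC had 8 and 2.

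**Figure D2:**
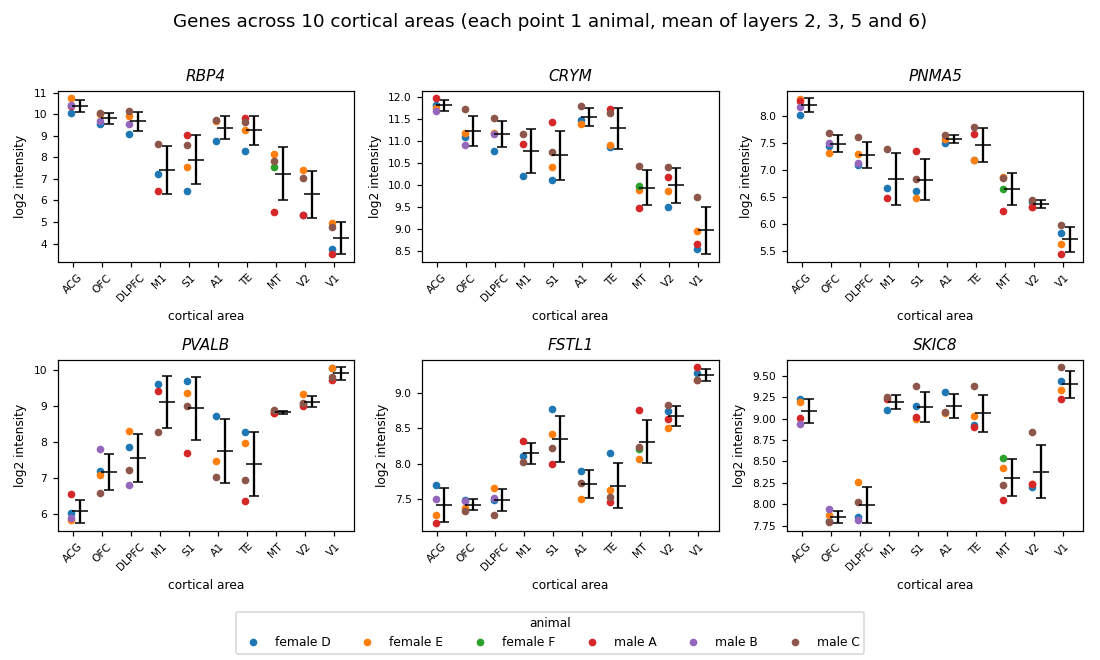
Expression of 6 genes in 10 cortical areas, as log2 intensity averaged over layers 2, 3, 5 and 6; points are animals and bars are the mean ± SD (3 or 4 animals). RBP4 was lowest in V1 (4.25) and highest in ACG (10.39), PVALB was highest in V1 (9.90) and lowest in ACG (6.07), and SKIC8 split by control set, from 9.06 to 9.40 in the narrow set and from 7.86 to 8.38 in the wide set.

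V1 against V2 asked what separates neighbouring visual areas. In V1, 7 genes were higher and 15 lower (2168 at adjusted p alone). CLMP was 3.42-fold higher (1.78 ± 0.18), CNTN5, a contactin adhesion molecule, was higher by 1.52 ± 0.25 and the adrenergic receptor ADRA2A by 1.06 ± 0.14; RBP4 (-2.03 ± 0.40), TWIST1 (-1.69 ± 0.19), LPAR6 (-1.29 ± 0.16) and CRYM (-1.02 ± 0.18) were lower. SKIC8 (1.02 ± 0.11) and HBB (-1.33 ± 0.19) were also called, and both differed among the array sets of the control pool (adjusted p = 0.000282 and 0.0235 in 15 arrays, with ranges of 0.997 and 0.932). Pool set 1, with the widest cre spread (0.162), had the highest SKIC8 (9.58) and the lowest HBB (7.54). V2, of the wide control set, had lower SKIC8 and higher HBB than V1, the reverse direction. The pool was used for scaling, so its differences are no measure of batch here. V1 lay in the narrow and V2 in the wide control set, so batch and area cannot be told apart for these genes.

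The difference between deep and upper layers was compared between V1 and the other 9 areas. It differed in 54 of 10286 genes, 35 with a larger and 19 with a smaller deep excess in V1 (84 at adjusted p alone). FREM3 (2.97 ± 0.20), SYT6 (2.91 ± 0.20), CRYM (2.54 ± 0.17), CNTN5 (2.17 ± 0.17) and WIF1 (1.90 ± 0.11) were shifted towards the deep layers of V1. NPY, a neuropeptide of inhibitory neurons (-2.04 ± 0.16), TWIST1 (-1.97 ± 0.10) and PCDH8 (-1.73 ± 0.13) were shifted towards its upper layers. Of 20 axon guidance genes, EPHA3 (1.48 ± 0.11) and SEMA3C (1.31 ± 0.15) were shifted towards the deep layers and 18 were not called (adjusted p = 0.162). The count fell whichever animal was left out: it was 25 without female D, 17 without female E, 14 without male A and 6 without male C. The full fit had only 3 residual degrees of freedom, so lost power and the influence of an animal cannot be told apart. With limma's trend and robust settings the count was 33.

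Within V1, 8 layers were sampled, and 1498 of 10218 genes differed among them (2624 at adjusted p alone). Layer 2 differed from the mean of the other V1 layers in 403 genes, 178 of them higher. PCDH8 was 24.9-fold higher there (4.64 ± 0.23), and CCN3 (3.09 ± 0.27) and TWIST1 (3.08 ± 0.17) were higher, while CRYM was 12.6-fold lower (-3.66 ± 0.23). Of 8 upper layer neurons genes, 5 were higher and 3 not called (adjusted p = 7.23e-07, and 0.00127 with an estimated correlation); of 6 myelin and oligodendrocytes genes, 4 were lower and 2 not called (adjusted p = 4.54e-09, and 0.0003 with an estimated correlation). Layer 3 had 72 genes higher and 54 lower, with CFAP52 at 2.73 ± 0.30 and PHLDB2 at -2.72 ± 0.46, and layer 4A had 16 and 8, with CD53 at 1.96 ± 0.21 and NPTX2, a pentraxin of excitatory synapses, at -2.36 ± 0.22.

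Layer 4B of V1, whose poly-A controls read highest of the V1 layers (10.61 ± 0.48, SD), had 40 genes higher and 133 lower. CENPF (3.20 ± 0.31), KCNH8, a potassium channel (2.44 ± 0.20), NHLH2 (2.11 ± 0.28), ACAN (1.18 ± 0.15), SPP1 (1.14 ± 0.19) and NEFH (1.02 ± 0.17) were higher, and EFNB2, an ephrin (-1.74 ± 0.20), and EGR2 (-1.31 ± 0.26) were lower. Among the 6 myelin and oligodendrocytes genes, 2 were higher and 4 not called (adjusted p = 3.72e-08, and 0.000595 with an estimated correlation). Of 5 large axon and magnocellular markers genes, 2 were higher and 3 not called (adjusted p = 9.88e-05, and 0.0215 with an estimated correlation). Of 7 fast spiking channels genes, 1 was higher and 6 not called (adjusted p = 4.34e-05, and 0.0164 with an estimated correlation).

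Layer 4Ca had 54 genes higher and 201 lower, and layer 4Cb had 126 higher and 55 lower. Among the V1 layers, the arrays of 4Ca correlated least with the other arrays of their group (mean 0.953, lowest 0.941). Those of 4Cb correlated most (mean 0.975), a limit on the contrasts of these layers. In 4Ca, NHLH2 (3.22 ± 0.28), CENPF (3.20 ± 0.31), PHLDB2 (2.99 ± 0.46), KCNH8 (2.98 ± 0.20) and MET (2.84 ± 0.33) were higher and CHRM3, a muscarinic receptor, was 10.2-fold lower. In 4Cb, CD48 (3.89 ± 0.29), ASB5 (3.67 ± 0.37), CRISPLD1 (2.96 ± 0.24), NTNG1 (2.23 ± 0.19) and RORB (1.16 ± 0.22) were higher. HTR2A, a serotonin receptor, was higher in both, by 1.17 ± 0.28 in 4Ca and 2.01 ± 0.28 in 4Cb, and was the 1 called gene of the 3 primary visual cortex genes in each, with 2 not called. That list held with an estimated correlation in 4Ca (adjusted p = 0.00718, and 0.0372 with an estimated correlation) and not in 4Cb (adjusted p = 0.0462, and 0.203 with an estimated correlation).

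Layer 5 of V1 had 78 genes higher and 74 lower, with NIF3L1 (3.62 ± 0.43), NEUROD6 (2.94 ± 0.24), FEZF2 (2.70 ± 0.25) and ETV1 (2.23 ± 0.36) higher and CUX2 lower (-4.04 ± 0.17). Of 8 layer 5 neurons genes, 4 were higher and 4 not called (adjusted p = 1.6e-08, and 0.000368 with an estimated correlation). Layer 6 had 175 higher and 121 lower; SYT6 was 87.2-fold higher (6.45 ± 0.25), FEZF2 11.5-fold and NPTX2 9.58-fold higher, and CUX2 was 41.4-fold lower (-5.37 ± 0.17), BHLHE22 28.1-fold and TAFA1 14.4-fold lower. HTR2A (-2.00 ± 0.28) and FSTL1 (-1.34 ± 0.09) were the 2 lower genes of the 3 primary visual cortex genes, with 1 not called (adjusted p = 2.88e-05, and 0.00266 with an estimated correlation). Of 10 layer 6 neurons genes, 4 were higher and 6 not called (adjusted p = 4.8e-05, and 0.00802 with an estimated correlation), and of 6 layer 4 neurons genes, 2 were lower and 4 not called (adjusted p = 0.000255, and 0.00862 with an estimated correlation).

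**Figure D3:**
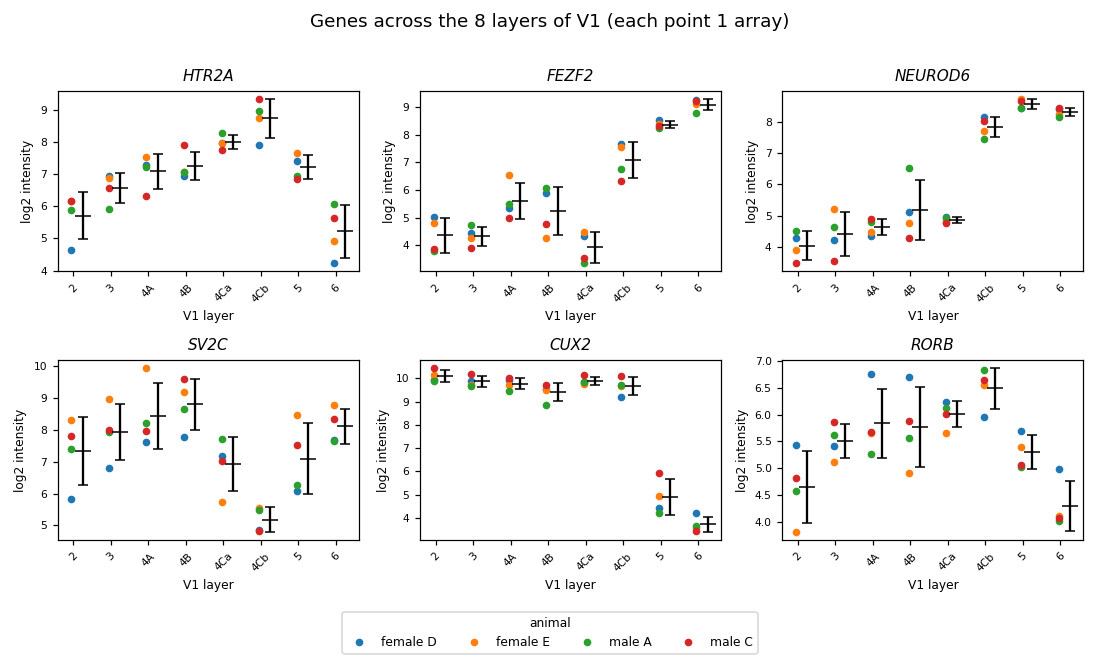
Expression of 6 genes in the 8 layers of V1, as log2 intensity; points are arrays, 1 per animal, and bars are the mean ± SD (4 arrays). CUX2 stayed between 9.41 and 10.10 from layer 2 to 4Cb and was at 4.88 in layer 5, HTR2A was highest in 4Cb (8.73), and FEZF2 and NEUROD6 were at 3.93 and 4.87 in 4Ca and at 7.07 and 7.83 in 4Cb.

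The contrast of 4Ca with 4Cb set the layer with magnocellular input against that with parvocellular input. In 4Ca 15 genes were higher and 124 lower, of 10218 tested (328 at adjusted p alone). INHBA (1.99 ± 0.55, adjusted p = 0.043, higher in 4 of 4 animals), CENPF (1.83 ± 0.41) and SV2C, a synaptic vesicle protein (1.74 ± 0.46), were higher in 4Ca. NIF3L1 was 12.7-fold higher in 4Cb, FEZF2 8.85-fold (-3.15 ± 0.33), NEUROD6 7.77-fold, RPRM 7.61-fold (-2.93 ± 0.19) and ETV1 6.26-fold higher. Of 19 axon guidance genes, EFNB2 (-1.41 ± 0.27), EPHB1 (-1.29 ± 0.18) and EFNB3 (-1.10 ± 0.26) were lower in 4Ca and 16 were not called, while 4 were called lower when adjusted over the list alone (adjusted p = 0.131). Of 8 layer 5 neurons genes, 2 were lower in 4Ca and 6 not called (adjusted p = 0.04, and 0.153 with an estimated correlation). Of the 124 genes higher in 4Cb, 93.5% were also higher in layer 5 than in 4Ca, against 57.2% of all genes. The count was 70 without female D and 58 without female E, and 89 with a second quantile normalisation.

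Layer 4C of V1 was compared with layer 4 of V2, where 167 genes were higher and 118 lower, of 10178 tested (1183 at adjusted p alone). ASB5 was 24.3-fold higher (4.60 ± 0.20), NHLH2 23.9-fold, PHLDB2 18.7-fold and CD48 17.5-fold higher in V1, with CUX2 (2.67 ± 0.14), NTNG1 (2.24 ± 0.14) and HTR2A (1.55 ± 0.18). TWIST1 was 19.5-fold lower (-4.28 ± 0.19), TSHZ2 12.7-fold and CD24 11.1-fold lower, as were VIP (-2.17 ± 0.24) and FEZF2 (-2.17 ± 0.20). Of 7 upper layer neurons genes, 3 were higher, 1 lower and 3 not called (adjusted p = 0.0215, and 0.64 with an estimated correlation), and of 8 layer 5 neurons genes, 2 were lower and 6 not called (adjusted p = 0.0128, and 0.64 with an estimated correlation). The areas lay in different control sets, so the size of a change cannot be told apart from batch; ASB5, CD48, NHLH2 and NTNG1 were also higher in 4Cb than in the other layers of V1, a comparison within V1.

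The hippocampal fields were compared to find the genes that mark each. Of 10249 genes, 1966 differed among the 4 fields (6580 at adjusted p alone). DG differed most, with 556 genes higher and 495 lower than the mean of the other fields. GRP was 128-fold higher there, the phosphatase PTPRS 43.8-fold, the receptor ADGRG2 43.3-fold, the proteoglycan VCAN 18.6-fold (4.22 ± 0.19) and PROX1, a transcription factor of granule cells, 12.5-fold higher (3.64 ± 0.10). NEUROD6 was 43.2-fold lower (-5.43 ± 0.21), CTXN3 42.3-fold and TRHDE 37.1-fold lower, and NECTIN3 was lower too (-5.04 ± 0.15). GRIK2 (2.04 ± 0.10) and GRIK1 (-2.78 ± 0.11), both kainate receptor subunits, moved in opposite directions. Of 4 dentate gyrus granule cells genes, 2 were higher, 1 lower and 1 not called, and the list was not called (adjusted p = 0.121). Of 8 layer 5 neurons genes, 6 were lower and 2 not called (adjusted p = 0.000811, and 0.188 with an estimated correlation). The myelin and oligodendrocytes list, with 6 tested, had 4 lower and 2 not called (adjusted p = 0.0291, and 0.289 with an estimated correlation). Of 9 microglia genes, 2 were lower and 7 not called (adjusted p = 0.0221, and 0.287 with an estimated correlation).

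CA1 had 167 genes higher and 190 lower. SH2D4B was 26.3-fold higher (4.72 ± 0.25), MET 11.9-fold (3.57 ± 0.19), and ETV1 (2.39 ± 0.17), POU3F1 (2.16 ± 0.11) and EGR2 (2.04 ± 0.27) were higher; TSPAN18 was 14.2-fold lower (-3.83 ± 0.16), and CPNE4 (-2.26 ± 0.20) and the serotonin receptor HTR7 (-2.09 ± 0.14) were lower. Of 3 CA1 pyramidal cells genes, 2 were higher and 1 not called (adjusted p = 0.0403, and 0.182 with an estimated correlation). CA2 had 155 higher and 132 lower. DKK2, a Wnt antagonist (3.88 ± 0.29), WNT2 (2.97 ± 0.17), HAPLN4 (2.59 ± 0.20), PVALB (1.92 ± 0.20), RGS14, a signalling regulator of CA2 neurons (1.46 ± 0.10), and ACAN (1.26 ± 0.19) were higher. GRP (-2.60 ± 0.13) and RBP4 (-2.01 ± 0.11) were lower. The other fields include DG, where GRP was far higher, so much of its lower value in CA2 reflects DG. RGS14 was the 1 called gene of 4 CA2 pyramidal cells genes, with 3 not called. It was also high in CA1, at 9.26 there and 9.81 in CA2, against 7.88 in CA3 and 7.92 in DG. POU3F1 was likewise at 7.49 in CA1 and 6.71 in CA2, against 4.67 in CA3 and 4.61 in DG. Of 8 perineuronal net and matrix genes, 3 were higher, 1 lower and 4 not called in CA2 (adjusted p = 0.0035, and 0.151 with an estimated correlation). VCAN of this list was at 7.20 in CA2, 7.30 in CA1, 6.84 in CA3 and 11.33 in DG. Its lower value in CA2 thus rests on DG.

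CA3 had 161 genes higher and 140 lower. TRHDE (3.33 ± 0.24), SHISA2 (2.70 ± 0.23), the adhesion molecule NECTIN3 (2.53 ± 0.15) and UGT8 (2.16 ± 0.17) were higher, and TMEM200A was 18.4-fold lower (-4.20 ± 0.24), GALNT1 8.73-fold lower and GABRA4 4.43-fold lower. The other fields include DG, which was low for several of these genes: TRHDE was at 11.28 in CA3, 10.82 in CA2 and 4.87 in DG, NECTIN3 at 10.65, 9.95 and 4.97, and UGT8 at 9.04, 8.47 and 5.34. All 3 CA3 pyramidal cells genes were higher, with CPNE4 at 1.45 ± 0.20 and BOK at 1.19 ± 0.11 (adjusted p = 0.000238, and 0.0565 with an estimated correlation). Of 6 myelin and oligodendrocytes genes, 3 were higher and 3 not called (adjusted p = 8.93e-05, and 0.0792 with an estimated correlation), and of 5 general neuronal transcripts genes, 1 was higher and 4 not called (adjusted p = 0.000896, and 0.0565 with an estimated correlation).

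**Figure D4:**
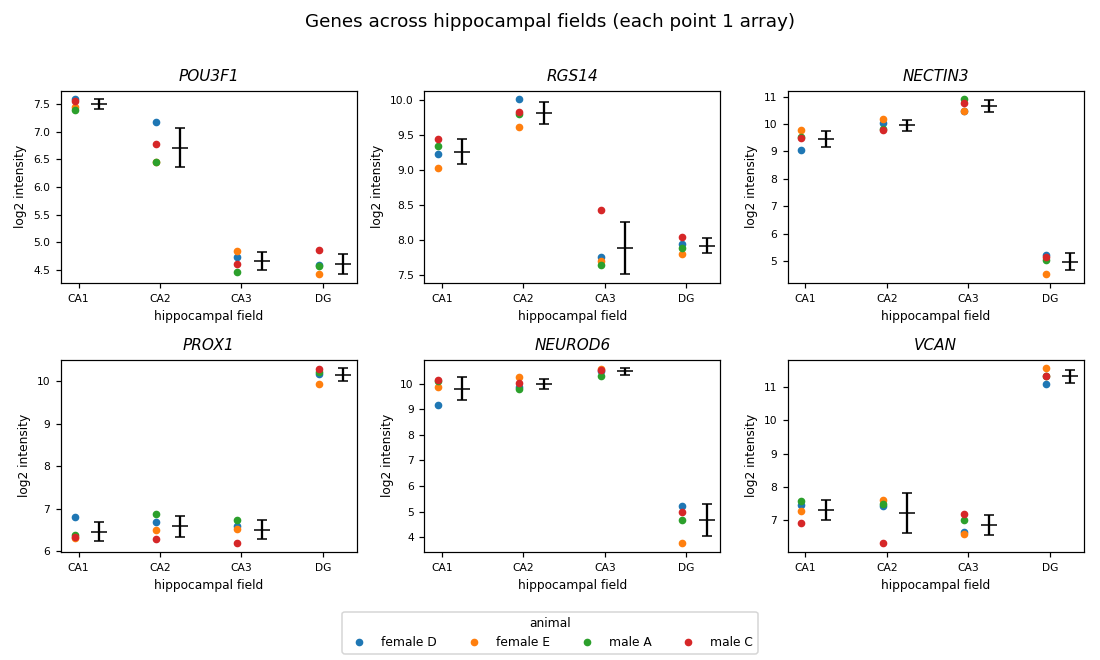
Expression of 6 genes in 4 hippocampal fields, as log2 intensity; points are arrays, 1 per animal, and bars are the mean ± SD (4 arrays). PROX1 and VCAN were at 10.16 and 11.33 in DG and no higher than 6.59 and 7.30 elsewhere, NEUROD6 and NECTIN3 were at 4.67 and 4.97 in DG, POU3F1 was highest in CA1 (7.49), and RGS14 was highest in CA2 (9.81).

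The divisions of the LGN were compared to set the cell classes of the visual thalamus apart. Of 10276 genes, 41 differed among them (315 at adjusted p alone), 19 without female E and 5 with no replicate block. In the magnocellular division 15 genes were higher and 16 lower than in the parvocellular division (92 at adjusted p alone). SLC12A1, an ion transporter, was 9.86-fold higher (3.30 ± 0.28), PWWP3B 9.50-fold, the channel gene ANO3 4.94-fold, SPON2 4.90-fold and the transcription factor EBF1 3.68-fold higher (1.88 ± 0.23). BHLHE22 was 4.95-fold lower (-2.31 ± 0.30), KCNB2, a potassium channel, 3.19-fold lower (-1.68 ± 0.21), INHBA 2.80-fold lower and BDNF, a neurotrophin, 2.61-fold lower (-1.39 ± 0.21). Of 9 immediate early genes, 1 was lower and 8 not called, with 4 lower at adjusted p alone, among them FOS (-0.90 ± 0.14); the camera call (adjusted p = 1.01e-08) was lost at adjusted p = 0.219 with an estimated correlation.

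The koniocellular division had 9 genes higher and 0 lower than the mean of the other divisions by limma (216 at adjusted p alone, 0 called and 17 at adjusted p alone without female E, and 0 called with no replicate block). They included CADPS2 (1.55 ± 0.35, adjusted p = 0.0324, higher in 4 of 4 animals), TAFA1 (1.47 ± 0.32), HTR7 (1.39 ± 0.29), CARTPT (1.31 ± 0.22) and CRYM (1.07 ± 0.25). Of 6 myelin and oligodendrocytes genes, 0 were called at the log2 threshold and 4 were higher at adjusted p alone, with UGT8 at 0.81 ± 0.13 and ENPP2 at 0.80 ± 0.10 (adjusted p = 1.57e-09, and 0.0941 with an estimated correlation). Of 9 microglia genes, 0 were called and 3 were higher at adjusted p alone (adjusted p = 0.000277, and 0.0941 with an estimated correlation), and of 7 astrocytes genes, 0 and 2 (adjusted p = 0.000416, and 0.422 with an estimated correlation). Of the koniocellular markers, 1 was tested and not called.

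**Figure D5:**
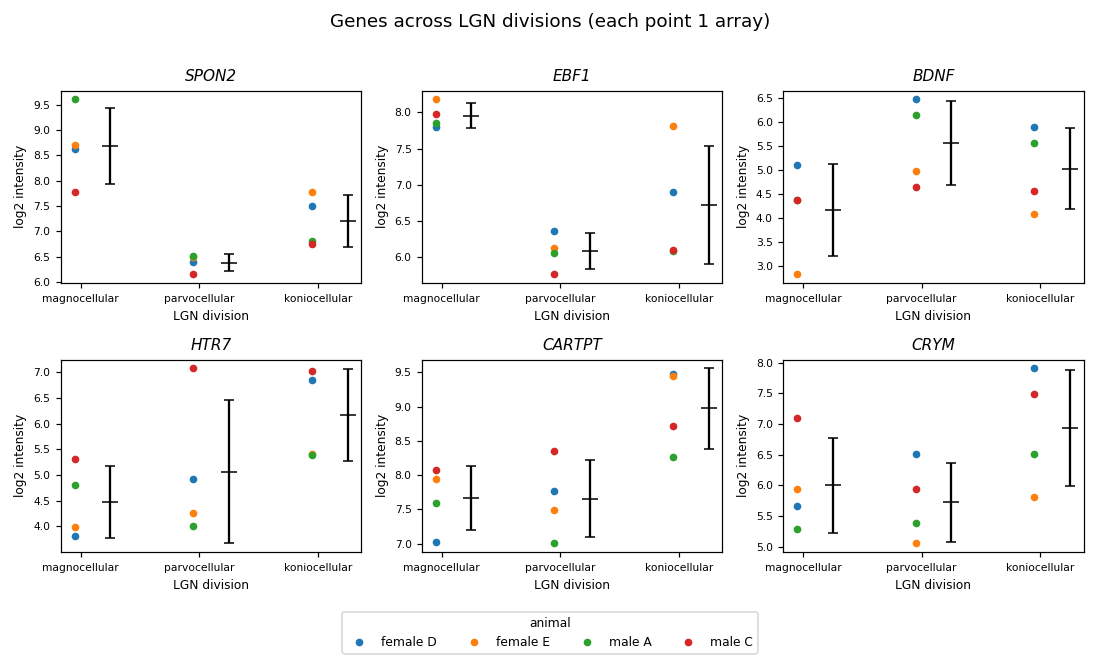
Expression of 6 genes in the 3 divisions of the LGN, as log2 intensity; points are arrays, 1 per animal, and bars are the mean ± SD (4 arrays). SPON2 and EBF1 were highest in the magnocellular division (8.68 and 7.96), CARTPT was highest in the koniocellular division (8.97), and BDNF was at 5.56 in the parvocellular and 4.18 in the magnocellular division.

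Cortex, hippocampus and LGN were compared as whole structures. Of 10320 genes, 1866 differed (8110 at adjusted p alone), and 1922 with only the cortical areas of the wide control set, to which hippocampus and LGN belonged. The LGN had 480 genes higher and 701 lower. STAR, a cholesterol transport protein, was 74.8-fold higher (6.23 ± 0.15), LCP1 65.2-fold, PVALB 42.4-fold (5.40 ± 0.09) and ADAMTS5 34.1-fold higher, with NEFH (3.63 ± 0.10), TCF7L2, a transcription factor of the Wnt pathway (3.33 ± 0.09), and RORA (2.86 ± 0.11). CKM, creatine kinase, was 195-fold lower (-7.61 ± 0.08), WIF1 129-fold, PCDH8 97.6-fold and SLC17A7, the cortical vesicular glutamate transporter, 13.3-fold lower (-3.74 ± 0.07). With the wide-set cortex, PVALB was at 5.39 ± 0.14 and STAR at 6.26 ± 0.17. Of 7 fast spiking channels genes, 6 were higher and 1 not called (adjusted p = 4.26e-05, and 0.123 with an estimated correlation). Of 20 axon guidance genes, 3 were higher, 11 lower and 6 not called (adjusted p = 0.00572, and 0.266 with an estimated correlation). Of 3 thalamic relay neurons genes, 2 were higher and 1 not called (adjusted p = 0.17), and of 3 glutamatergic identity genes, 2 were lower and 1 not called (adjusted p = 0.0162, and 0.233 with an estimated correlation).

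The hippocampus had 466 genes higher and 454 lower. MED14 was 57.1-fold higher (5.84 ± 0.07), under a symbol of the array annotation that was not checked against the genome, AQP3, a water channel, 33.2-fold, RBP4 29.8-fold and GRIA1 14.7-fold higher (3.87 ± 0.08), and PVALB was 23.1-fold lower (-4.53 ± 0.09), CUX2 11.9-fold and GRIA4 6.45-fold lower. Of 6 serotonin receptors genes, HTR7 (2.97 ± 0.25), HTR1A (1.64 ± 0.13) and HTR1E (1.10 ± 0.07) were higher and 3 not called (adjusted p = 0.333). Of 7 fast spiking channels genes, 5 were lower and 2 not called (adjusted p = 4.05e-05, and 0.122 with an estimated correlation). The cortex had 326 genes higher and 127 lower, with TESPA1 23.8-fold (4.57 ± 0.05), VIP 10.3-fold (3.36 ± 0.08) and EGR2 10.1-fold higher (3.33 ± 0.19) and LCP1 11.6-fold lower. The references of cortex and of hippocampus include the LGN, where LCP1 and PVALB were far higher. Much of the lower LCP1 in cortex, and part of the lower PVALB in hippocampus, thus reflects the LGN. Of 10 immediate early genes, 5 were higher and 5 not called (adjusted p = 0.00016, and 0.354 with an estimated correlation).

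Males and females were compared in 2 animals each. No gene was called by limma, 0 of 10306 passed adjusted p under 0.05, and 726 had an unadjusted p under 0.05. The highest by moderated t were ZSCAN29 (0.86 ± 0.07, adjusted p = 0.415, 4 animals), NUDCD1 (0.70 ± 0.05) and RSPH9 (0.74 ± 0.06), and the lowest were FGF14 (-0.51 ± 0.05), MET (-0.99 ± 0.09) and SCN8A (-0.76 ± 0.06). The genes on the sex chromosomes fixed beforehand had no probe set with their symbol. With 2 animals per sex, a log2 change of 1 added to simulated genes was recovered at adjusted p in 88.1% and called in 32.8%. The simulation held 200 changed genes, with changes of 1, 1.5 and 2, which eases the adjustment. These shares do not carry over to a contrast with few changed genes. In the real data MET did not pass at -0.99 ± 0.09.

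The whole brain RNA pool, the same material on 15 arrays in 3 array sets, was compared across the sets. The authors scaled each probe set on these pool samples, and the differences of the pool and of the CA3 control arrays between set 2 and set 3 cancelled at all 52865 probe sets (tolerance 1e-04), so the pool is no measure of the background between batches. Of 9947 genes, 1 was called, 17 passed adjusted p alone and 705 had an unadjusted p under 0.05. The called gene was VIM, a filament protein, named after its values were seen (adjusted p = 0.0232, range 1.01), with means of 9.62 ± 0.21 (SD, 6 arrays), 8.97 ± 0.36 (SD, 6 arrays) and 8.61 ± 0.16 (SD, 3 arrays). SKIC8 was at 9.58 ± 0.22, 8.59 ± 0.18 and 8.69 ± 0.16 (SD) in the same sets and stayed just under the range of 1.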

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

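The tests against amplification batch, against layer 5 tissue in the subset of genes above layer 5, and against fewer neurons in layer 6 were chosen only after the result was seen; the tests on poly-A controls, layer 5 tissue over all genes and splits of the samples were chosen before.

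V1 had mostly lower genes, 111 of 123. Amplification batch was tested because the control probes of V1 differed from those of the wide control set, and all 123 genes kept their direction at adjusted p under 0.05 against areas of the same control set. The test cannot tell, since the control set is a stand-in for batch, the hybridisation controls of V1 (12.5) lay apart from the rest of its set (11.4 to 11.8), and the contrasts share the V1 arrays. Lower RNA input was tested because poly-A controls read 0.94 higher in V1 than in the other areas. The slope on these controls came from 145 arrays of the other areas without V2. It predicted -1.99% of the change (-5.07% to 1.18% when animals were left out). V2 was the only other area with a mean near that of V1 (9.83 and 9.99, against 8.47 to 9.33). The slope speaks against lower RNA input only as far as it holds at the poly-A level of V1. A batch of V1 alone, lower RNA input outside the range of that slope and a difference of the area stay open.

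In the V1 layer 4Ca and 4Cb contrast, 124 genes were higher in 4Cb. Layer 5 tissue captured with 4Cb would give such genes, and 19.4% of them (24) had a layer 5 level that exceeded 4Ca by under 50% of the 4Cb excess, so the test cannot tell. The highest V1 level was in 4Cb for 42 of the 124, in layer 6 for 33, in layer 5 for 24 and in layer 2 for 19. For 15 of the genes, the level in 4Cb was above that in layer 5 at adjusted p under 0.05, among them CRISPLD1 (3.39 ± 0.31), which speaks against it for those genes. The slope on the poly-A controls, taken within all V1 layers, predicted 5.64% of the change. The 4Ca arrays hardly differed in poly-A level (SD 0.056), so the slope speaks against lower RNA input only as far as it holds in 4Ca. With the poly-A level as a covariate, 95 genes were called in either direction, against 139 without it. At adjusted p alone, 166 passed, against 328.

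In layer 6, 4 of 6 genes of the myelin and oligodendrocytes list were called higher (median 1.19), and the camera call was lost with an estimated correlation (adjusted p = 0.0556). Fewer neurons with more of every other cell type would raise the astrocytes, microglia and endothelium lists too. The astrocytes median was -0.387, with 5 of 7 lower and 2 higher at adjusted p alone. The microglia median was 0.0868 (3 of 9 higher and 1 lower) and the endothelium median 0.0135 (2 of 6 higher and 0 lower). The medians speak against a rise of every other cell type, though some microglia and endothelium genes were higher. The slope on the poly-A controls predicted 0.506% of the change, which speaks against lower RNA input.

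Splits of the samples within animals asked whether a grouping at random gave as many called genes. Of 100 splits, counting the real one, only the real one (1) reached its count among layers 2 to 6 (681, highest other 397), deep against upper layers (219, 31), the 10 areas (947, 107) and V1 (123, 99). The same held for V1 and V2 against frontal areas (152, 43), the layers of V1 (1498, 77), 4Ca against 4Cb (139, 128) and hippocampal fields (1966, 1723). It also held for LGN divisions (41, 16), magnocellular against parvocellular (31, 17) and the structures (1866, 1066). The smallest share that 100 splits can give is 1 in 100, and many comparisons were tested. Labels moved among levels that differ, and for V1, 4Ca against 4Cb and hippocampal fields another split came near. Chance is made less likely by these counts but is not excluded. The koniocellular contrast had 2 of 100 (9, highest other 22), the pool had 2 of 100 (1, highest other 1) and V1 against V2 had 2 of 100 (22, highest other 132), a share under 0.05, though 1 other split gave as many or more in each. The koniocellular count was 0 without female E. The highest other count of V1 against V2 (132) was several times the real one. The splits exchange the labels of all 10 areas, and other pairs of areas differed in more genes (ACG and V1, 420). Which split gave 132 was not examined, so its cause was not tested. The laminar difference in V1 (1 of 32, real 54, highest other 0) and layer 4C of V1 against layer 4 of V2 (1 of 32, real 285, highest other 0) had too few splits that part all 4 pairs (8).

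Single animals stood apart in 6 of 102 tested groups of values, and the rule marks about 1 in 20 groups by chance. HBB in V1 against V2 was at -0.0106 in 1 animal against -1.82 to -1.69 in the others. GASK1B in V1 and V2 against frontal areas was at 3.11 against 1.48 to 1.74. ANO5 in the same contrast was at 2.53 against 1.42 to 1.57. CNTN5 in the laminar difference was at 1.55 against 2.33 to 2.42. WIF1 in the laminar difference was at 1.81, below the others at 1.93. SV2C in 4Ca against 4Cb was at 0.18 against 2.20 to 2.33. The difference between deep and upper layers differed between V1 and the other areas in 54 genes. A reporter probe set read above 16 in 49 experimental arrays, all of them among the 104 of the wide control set and none among the 121 of the narrow set, and in 0 of 27 control arrays, whose highest value was 14.5.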

How the results depend on the processing

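The poly-A covariate and the comparisons within control sets were chosen after seeing the data, and the other alternatives in these paragraphs before it. Most counts stayed within a factor of 1.5 of their value. With no filter all 19 counts stayed, as did all 9 with each array as a unit and all 17 called counts with the poly-A control level as a covariate. With that covariate the counts at adjusted p alone fell from 4603 to 1775 for V1, from 4401 to 1419 for V1 and V2 against frontal areas, from 84 to 42 for the laminar difference in V1, from 328 to 166 for 4Ca against 4Cb, from 1183 to 771 for layer 4C of V1 against layer 4 of V2, from 315 to 198 among LGN divisions and from 92 to 54 for magnocellular against parvocellular. Of 976 values of named genes, 0 reversed in 11074 alternative values and 609 were weaker. Most of these genes were chosen because they were called, many with the same direction in every animal, so few reversals could occur. The filters and the trend and robust settings leave the size of a change as it is. The lack of reversals is therefore no test of the named genes.

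Filtering at the 75th percentile tested fewer genes by construction, and the counts fell from 681 to 452 among layers 2 to 6, from 219 to 143 for deep against upper layers, from 947 to 597 among the 10 areas, from 285 to 176 for layer 4C of V1 against layer 4 of V2, from 41 to 24 among LGN divisions, from 31 to 18 for magnocellular against parvocellular and from 9 to 3 for the koniocellular division. Taking the mean of each gene's probe sets gave 139 for deep against upper layers, 540 among the 10 areas, 141 for any area against the others, 80 for V1, 13 for V1 against V2, 96 for V1 and V2 against frontal areas, 83 for 4Ca against 4Cb, 183 for layer 4C against layer 4 of V2, 25 among LGN divisions, 19 for magnocellular against parvocellular and 0 for the pool (10 at adjusted p alone); the cause was not tested.

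With no replicate block the LGN counts fell to 5 among divisions, 7 for magnocellular against parvocellular and 0 for the koniocellular division, while the other 14 counts stayed; animal differences then enter the residual by construction. The trend and robust settings gave 33 genes for the laminar difference in V1 (54), and a second quantile normalisation gave 89 for 4Ca against 4Cb (139); the cause was not tested. V1 against areas of its own control set had 216 genes (123), and the areas of the wide control set differed in 145 (947), with 4 areas compared in place of 10. The estimated correlation left 30 of 230 gene set calls. It allows for correlation between list members, but whether that removed the other calls was not tested.

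Leaving out 1 animal gave 6 to 25 for the laminar difference in V1 (54), 58 to 157 for 4Ca against 4Cb (139), 19 to 59 among LGN divisions (41) and 0 to 12 for the koniocellular division (9), with 8 such counts moved and 75 not. Simulated data of the same size held 200 changed genes. A log2 change of 1 reached adjusted p under 0.05 there in 92.5% of genes for the laminar difference. The share was 83.6% for 4Ca against 4Cb and 79.1% among LGN divisions. The simulated noise of a gene was the same in every array. The real V1 arrays correlated least with their group (mean 0.966), so the shares for V1 contrasts may be too high. The ranges elsewhere were 660 to 704 among layers, 215 to 227 for deep against upper layers, 944 to 1046 among areas, 115 to 152 for V1, 19 to 32 for V1 against V2, 265 to 339 for layer 4C and 1929 to 2050 among hippocampal fields.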

Other observations

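No test in these paragraphs was chosen only after the result was seen.

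Several genes recurred across structures with different roles. MET marked layer 3 of cortex (1.89 ± 0.19) and CA1 (3.57 ± 0.19) and was lower in layer 6 (-2.85 ± 0.19), and TE had more of it (1.97 ± 0.24) than other areas. NEUROD6 was lower in layer 2 (-3.22 ± 0.13), DG (-5.43 ± 0.21) and LGN (-4.16 ± 0.08), with 10.48 in CA3, 10.00 in CA2, 9.82 in CA1 and 4.67 in DG. GRP was higher in layer 5 (2.01 ± 0.13), ACG (2.17 ± 0.14) and DG. Its lower value in CA2 (-2.60 ± 0.13) was taken against a mean that includes DG, and much of it reflects the high level there. BHLHE22, a transcription factor, was lower in layer 6 (-3.46 ± 0.10) and in the magnocellular division (-2.31 ± 0.30) and higher in A1 (1.27 ± 0.19).

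HAPLN4, a link protein of the matrix, was higher in CA2 (2.59 ± 0.20), M1 (1.20 ± 0.16) and the visual areas against frontal areas (1.19 ± 0.13), and lower in DG (-2.93 ± 0.20) and layer 2 (-1.19 ± 0.12). VCAN was higher in DG (4.22 ± 0.19). Its lower value in CA2 (-1.29 ± 0.19) reflected DG among the other fields. The levels were 7.20 in CA2, 7.30 in CA1, 6.84 in CA3 and 11.33 in DG. In CA2 the same tissue also held more PVALB (1.92 ± 0.20) and NEFH (1.79 ± 0.12).

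Frontal and visual cortex were set apart by opposite genes: RBP4 was higher in ACG (2.71 ± 0.31) and lower in V1 (-4.31 ± 0.30), and PVALB was lower in ACG (-2.41 ± 0.27) and higher in V1 (1.92 ± 0.26). PVALB did not follow a single direction along the cortex, since it was also higher in M1 (1.10 ± 0.30).

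New animals would be needed for the laminar difference in V1, whose count ranged from 6 to 25 without 1 animal, and for the koniocellular division. A direct test of V1 against V2 needs arrays of both areas processed in a single batch.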
